A study of Homo sapiens with 2 samples.

How the data were processed

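Single-cell RNA sequencing was used to profile brain organoids grown to day 28 from H1, an established human embryonic stem cell line. The series holds 2 libraries, 1 from wildtype organoids and 1 from FEZ1 knockout organoids, each made with the droplet-based 10x Genomics 3′ chemistry, which counts unique molecular identifiers (UMIs) at transcript 3′ ends. Groups were taken from the genotype given in the labels.

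The values used were the raw UMI counts per gene and barcode as deposited, with no scaling. They came from Cell Ranger 3.1.0, per the submitters' processing notes and per the file headers. The submitters' processing notes also named Seurat 3.1, Partek and the builds GRCh38 and hg19, without a role for any of them. The aligner settings and the annotation release were not given in the sources used here. Each library listed the same 33538 genes, and the smallest barcode total was 500 UMIs in both. Of these gene identifiers, 33456 were in GENCODE release 29 on GRCh38, 33071 of them under the same symbol. That annotation was used for the position of FEZ1 only.

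Barcodes were kept with at least 500 detected genes and at most 15% mitochondrial UMIs, which left out 358 wildtype and 430 knockout barcodes. Doublets were scored with Scrublet, as included in scanpy 1.11.5, and the top-scoring share was removed, set to 0.8% per 1000 barcodes. This took out 560 of 8189 wildtype and 809 of 9846 knockout barcodes. Scrublet's automatic threshold marked 3 wildtype barcodes (0.0366%), too few to have worked, and 431 knockout barcodes (4.38%), so the fixed share was used in both. Counts were scaled to 10000 per cell, log-transformed and reduced to 2000 highly variable genes, scaled values being clipped at 10. Clustering used 30 principal components, 20 neighbours, a shared-neighbour graph pruned at a Jaccard index of 1/15 and the Leiden algorithm at resolution 1.0, on both libraries jointly with no batch correction.

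Clusters were named from markers of 16 cell types fixed before the data were examined. The rule that turned markers into names was set and revised with the clusters in view. A first form took the type with the highest mean marker fold. It was changed because it put cluster 22, a dividing cluster led by hem genes, among the dividing cells, and it would have named cluster 15, of few UMIs, as dividing. The rule used compared each cluster with the equal-weight mean of the other clusters, adding 5 CPM. It required at least 3 markers 1.5-fold higher at 10 CPM or more and a mean marker log2 fold of at least 0.25. The type with the most markers among the top 10 genes (of at least 50 CPM) was chosen, then the highest mean fold. A cluster whose median UMI count was under 1/3 of that of its cells' libraries needed 3 of its own markers in the top 10. Cajal-Retzius and GABAergic neurons were counted as kinds of neuron, a choice also made with the clusters in view. The 5 clusters left unnamed held 15.6% of wildtype and 19.4% of knockout cells. Cluster 22 held 2.03% of wildtype and 0.697% of knockout cells.

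With 1 library per group no test across samples was possible, so no p-value, standard error or count of significant genes is given. UMIs were summed per library, or per library and class, and expressed as CPM, counts scaled to the same library total. CPM values carry exact Poisson intervals, log2 ratios of knockout over wildtype exact conditional intervals, and shares of cells exact Clopper-Pearson intervals, all at 95%. A count of 0 was given a floor of 3 counts, in place of the exact upper limit for shares of cells too. These intervals and floors cover counting error only, not the spread between organoids or library preparations. A size rule took the place of a test: at least 1.5-fold either way among genes with a mean of at least 10 CPM. Folds within a class were computed where both libraries held at least 100 cells of it. The median log2 ratio of all genes was 0.04 in the whole library.

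The genes named were chosen by a rule set beforehand: FEZ1, the 10 largest log2 ratios each way in the whole library and the 5 largest each way in radial glia-like and neuron-like cells at a mean of at least 50 CPM, and up to 4 members per gene list with the largest ratios at 10 CPM or more. Mitochondrial, ribosomal protein, sex-linked marker and clone-named genes were left out of all but the lists. Some genes that the rule selects are not reported here. FEZ2, the genes used to describe single clusters, the values inside single clusters and in classes other than radial glia-like and neuron-like cells, and the keratin-led cluster were chosen after their values were seen. For the 33 gene lists fixed beforehand, holding 809 genes of which 807 were among the feature symbols, the median log2 ratio was set against 10000 random lists of the same size matched in 20 bins of mean expression. Its percentile describes these 2 libraries alone. To compare shares of cells with a UMI, each cell was thinned to 3000 UMIs, which left out 509 wildtype and 1036 knockout cells.

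The folds, size rule, intervals and list percentiles were tested on simulated counts with the real genes and library sizes, 50 genes being moved by each of 4 sizes. Counts were Poisson draws from a profile shared by both libraries. The intervals assume that model, so their coverage and the few false calls were largely built in. No spread between cells or organoids was simulated, nor were clustering, naming or thinning. In the whole-library simulation over 8709 genes, the size rule took 0 of 50 genes at 1.25-fold, 21 at 1.5-fold, 46 at 2-fold and 47 at 4-fold. It took 0 of 8521 genes that were not moved, the intervals covered 95.2% of true values, and 9 of 200 random lists lay outside the middle 95%. For radial glia-like cells, over 8481 genes, it took 0, 24, 47 and 47 genes at those sizes, and for neuron-like cells, over 8644 genes, 5, 22, 48 and 43, with 2 genes that were not moved.

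Alternatives tried were other cell filters, doublets kept, other Leiden resolutions, library-wise centring, clustering without genes 2-fold apart, a per-cell marker score, other scalings, minimum levels and weights of cells, 1 class mix in both libraries, and other depths. Leaving out groups of clusters, a denominator of named cells and the per-cell mean for gene lists were added after seeing the data. Software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, python-igraph 0.11.9 and matplotlib 3.10.9.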

Results

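Brain organoids are three-dimensional cultures in which stem cells form neural progenitors and neurons. The series asked how loss of FEZ1, an adaptor protein of kinesin-1 transport that is needed for axon outgrowth, alters the progenitors and neurons of such organoids at day 28. It compared 1 wildtype library with 1 FEZ1 knockout library. The wildtype library held 8547 barcodes and 99936323 UMIs, with medians of 10137 UMIs and 3209 genes per barcode. The knockout library held 10276 barcodes and 86517525 UMIs, with medians of 7143.5 UMIs and 2592 genes. After filtering, 7629 wildtype and 9037 knockout cells remained, at median depths of 10120 and 7092 UMIs. There were no replicates, so every difference reported separates these 2 libraries and has no replicate check.

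FEZ1 transcripts were lower in the knockout library but not lost. FEZ1 (ENSG00000149557; GRCh38 chromosome 11, 125442881 to 125592568, minus strand, protein coding) stood at 117 CPM in wildtype (95% interval 115 to 120) and 27.7 CPM in the knockout (26.5 to 28.9). The log2 ratio was -2.08 (-2.15 to -2.02), and the knockout level was 23.6% of wildtype (22.5 to 24.7). Wildtype neuron-like cells carried the most FEZ1 among the compared classes, at 315 CPM against 57.2 CPM in knockout neuron-like cells, a log2 ratio of -2.46 (-2.60 to -2.33). In radial glia-like cells, the neural stem cells of the organoid, the levels were 118 and 22.9 CPM (log2 ratio -2.37, -2.48 to -2.25). The ratio was nearer to 0 in choroid plexus-like cells, at -1.39 (-1.90 to -0.91). FEZ2, the paralogue of FEZ1, stood at 47.5 CPM in wildtype and 51.1 CPM in the knockout. The edited position was not given in the sources used here, and a 3′ tag can lie outside an edit, so the FEZ1 level is not by itself a check of the genotype.

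At 3000 UMIs per cell, 28.8% of wildtype cells (27.8 to 29.9) and 8.09% of knockout cells (7.498 to 8.706) had a FEZ1 UMI. Among neuron-like cells the shares were 59.3% (55.8 to 62.8) and 15.01% (13.08 to 17.10). Choroid plexus-like cells, the secretory epithelium that makes cerebrospinal fluid and the one of the 6 compared classes with the least FEZ1, gave 10.2% in wildtype and 3.48% in the knockout, at median depths of 13339 and 9517.5 UMIs before thinning. Neuron-like cells had median depths of 7619.5 and 4811 UMIs. Without thinning, 60.7% of wildtype and 18.7% of knockout cells had a FEZ1 UMI. For a measure of free RNA in the droplets, TTR, a carrier protein secreted by choroid plexus, was found in 10.6% of wildtype and 3.68% of knockout radial glia-like cells at 3000 UMIs, beside whole-library levels of 4942 and 1402 CPM.

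**Figure D1:**
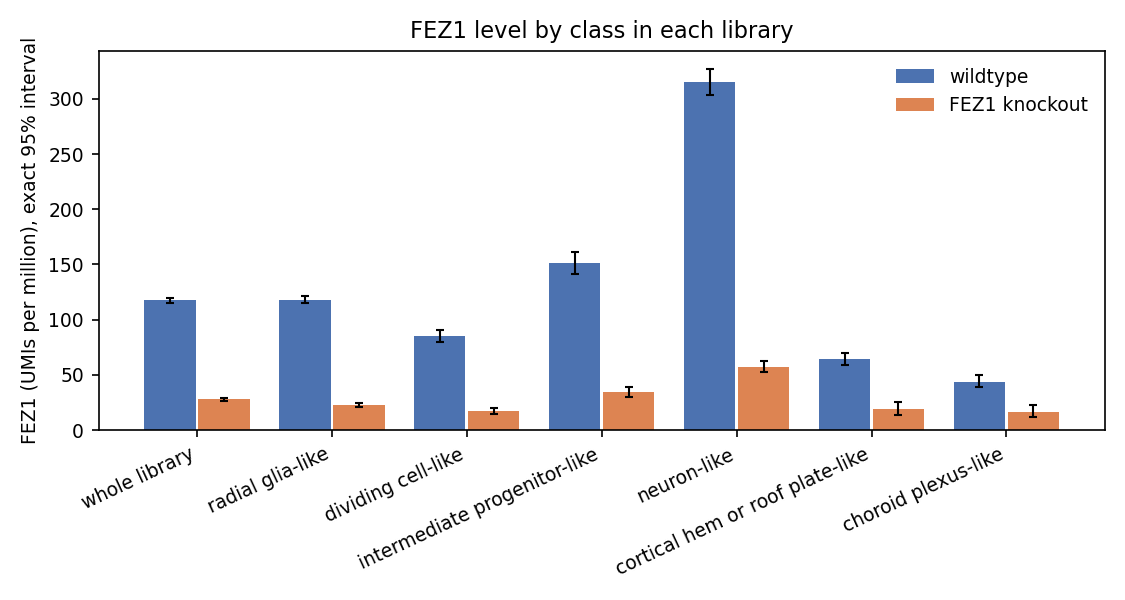
FEZ1 level in CPM for the whole library and 6 classes, in wildtype and FEZ1 knockout; bars are 1 library each and error bars are exact 95% Poisson intervals that cover counting error only. Neuron-like cells stood at 315 CPM in wildtype and 57.2 CPM in the knockout.

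Among the named classes, the shares of 3 differed most in percentage points. Neuron-like cells made up 11.74% of wildtype cells and 18.96% of knockout cells, 7.21 percentage points more (6.12 to 8.30). Of these points 3.02 lay in a cluster led by stress genes with 9 of 18 neuron markers raised but 0 among its top 10 genes. Most of it was unnamed or intermediate progenitor-like at resolution 2.0, where the neuron-like difference was 3.14 points. Cells like the cortical hem or roof plate, dorsal midline centres that secrete Wnt and BMP signals, made up 9.58% (8.93 to 10.3) and 2.66% (2.33 to 3.01), a share 3.61-fold lower in the knockout. Choroid plexus-like cells, a tissue that arises beside the hem, made up 5.70% (5.19 to 6.25) and 2.41% (2.11 to 2.75), 2.36-fold lower. Intermediate progenitor-like cells, the transit stage between radial glia and neurons, made up 7.63% (7.04 to 8.25) and 8.64% (8.07 to 9.24), a difference of 1.01 points that ranged from 0.146 to 2.94 points over the alternatives.

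Radial glia-like cells were the largest class, with 39.0% of wildtype cells (37.9 to 40.1) and 36.5% of knockout cells (35.5 to 37.5). Its cluster led by CHAC1, a stress gene, held 12.1% and 10.2% of cells, with 5 of 16 radial glia markers raised and 0 among its top 10 genes. At resolution 2.0, 227 wildtype and 204 knockout cells of that cluster were unnamed. Clusters 4, 5 and 19 of this class also had 0 markers among their top 10 genes. Dividing cells held 8.93% (8.30 to 9.59) and 9.48% (8.89 to 10.1), a difference of 0.56 points whose interval reached from -0.33 to 1.44. Mesenchyme or neural crest-like cells, marked by collagens, made up 0.341% and 0.963%, and pigment epithelium-like cells, marked by melanin genes, were 2 wildtype and 53 knockout cells. Non-neural epithelium-like cells made up 1.49% and 0.476% at the resolution used. At resolutions 0.5 and 2.0 the cluster led by keratins held 0 wildtype cells and 17 knockout cells, and at 2.0 the rest of this class, 114 wildtype and 26 knockout cells, was hem-like. The 5 unnamed clusters held 15.6% of wildtype and 19.4% of knockout cells, and a different share of unnamed cells moves every other share. The direction for radial glia-like cells depended on the processing: the difference was -2.50 points as clustered, 0.0837 points with stricter cell filters and 2.37 points with a per-cell marker score. That for dividing cells turned with those filters (-2.34 points), with that score (-2.11 points) and with no cell filter (-0.831 points). The choroid plexus-like difference of -3.29 points was -6.02 points at resolution 0.5, -2.33 points when clustered without genes 2-fold apart between the libraries and -1.99 points with no cell filter.

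**Figure D2:**
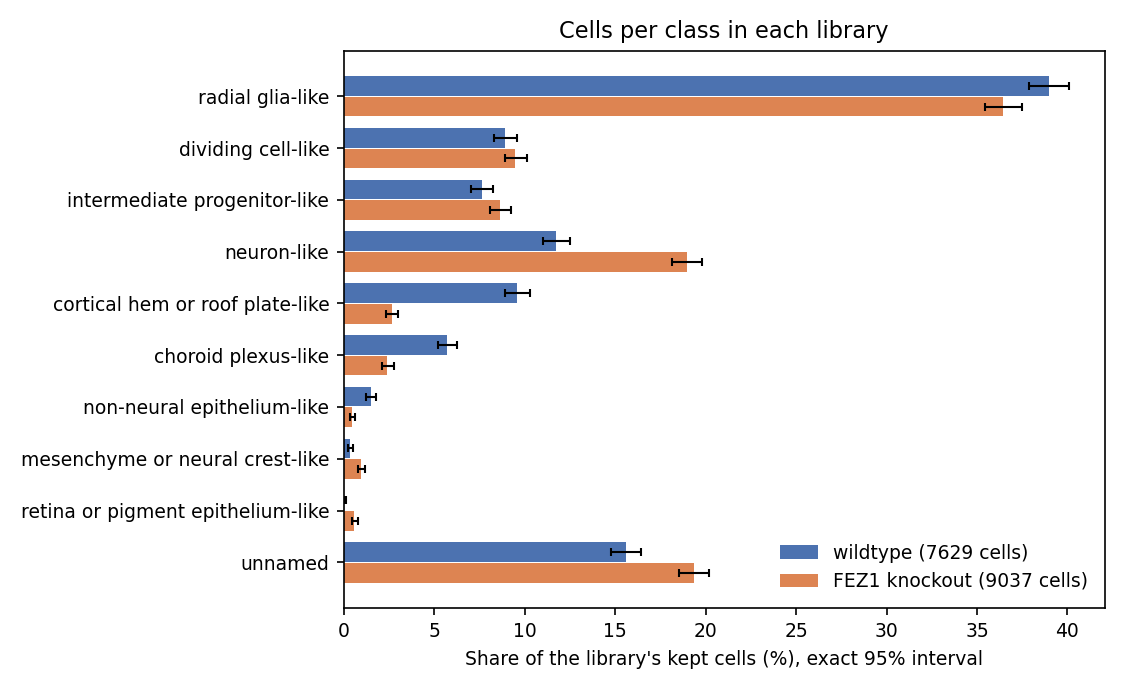
Percent of kept cells in each class, in wildtype (7629 cells) and FEZ1 knockout (9037 cells); bars are 1 library each and error bars are exact 95% binomial intervals for counting error only. The neuron-like share was 11.74% in wildtype and 18.96% in the knockout, and the cortical hem-like share 9.58% and 2.66%.

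The neuron-like cells of the 2 libraries were spread differently over the same clusters. A cluster led by NEUROD6 and RELN, genes of early cortical and Cajal-Retzius neurons, held 468 wildtype and 319 knockout cells. Knockout neuron-like cells lay more in a cluster led by the stress genes ATF5 and DDIT3 (222 wildtype, 536 knockout cells), a cluster led by BARHL2 and LHX9 (80 and 318), a GABAergic cluster led by DLX genes (100 and 305) and a cluster led by HOXB genes and neurofilaments (26 and 235). The naming rule took the BARHL2 and LHX9 cluster, like the NEUROD6 and RELN cluster, as Cajal-Retzius neurons. Radial glia-like cells included a cluster led by SLC1A3, PMP2 and BNIP3 with 15 wildtype and 236 knockout cells. At resolution 2.0, 3 and 196 of these lay in a radial glia-like cluster led by the same genes, and 12 and 37 in a choroid plexus-like cluster led by CCNO. A cluster that is mostly 1 library may mark that library and not a cell type. In the GABAergic cluster DLX5 stood at 51.4 CPM in wildtype and 450 CPM in knockout cells, and NEUROD6 at 398 and 110 CPM. At resolution 2.0, 6 of its 100 wildtype and 109 of its 305 knockout cells lay in the cluster led by DLX genes, and 93 and 193 in an unnamed cluster of neurons with few UMIs.

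HOXB5, a homeobox gene of the hindbrain and spinal cord, had 0 UMIs in the wildtype library and 1577 in the knockout library. A UMI of it was found in 0 of 7629 wildtype cells, which allows a share of up to 0.0393%, and in 410 of 9037 knockout cells (4.54%, 4.12 to 4.99). Its CPM was at least 623-fold higher in the knockout. HOXB6 had 0 and 411 UMIs, at least 162-fold higher, and HOXB2 had 80 and 538 UMIs. At 3000 UMIs per cell, HOXB5 was found in 9.16% of knockout neuron-like cells and 2.14% of knockout radial glia-like cells, at median depths of 4811 and 8246 UMIs, and in 2.49% of knockout choroid plexus-like cells (0.813 to 5.71), at 9517.5 UMIs. Choroid plexus also forms in the hindbrain, so no class was taken as lacking the gene. In the radial glia-like cluster led by SLC1A3, 54 of 236 knockout cells had a HOXB5 UMI, against 18 of 1176 in the cluster led by SNHG12. Unthinned shares in knockout cells were 10.1% in neuron-like, 3.76% in radial glia-like and 3.21% in choroid plexus-like cells.

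**Figure D3:**
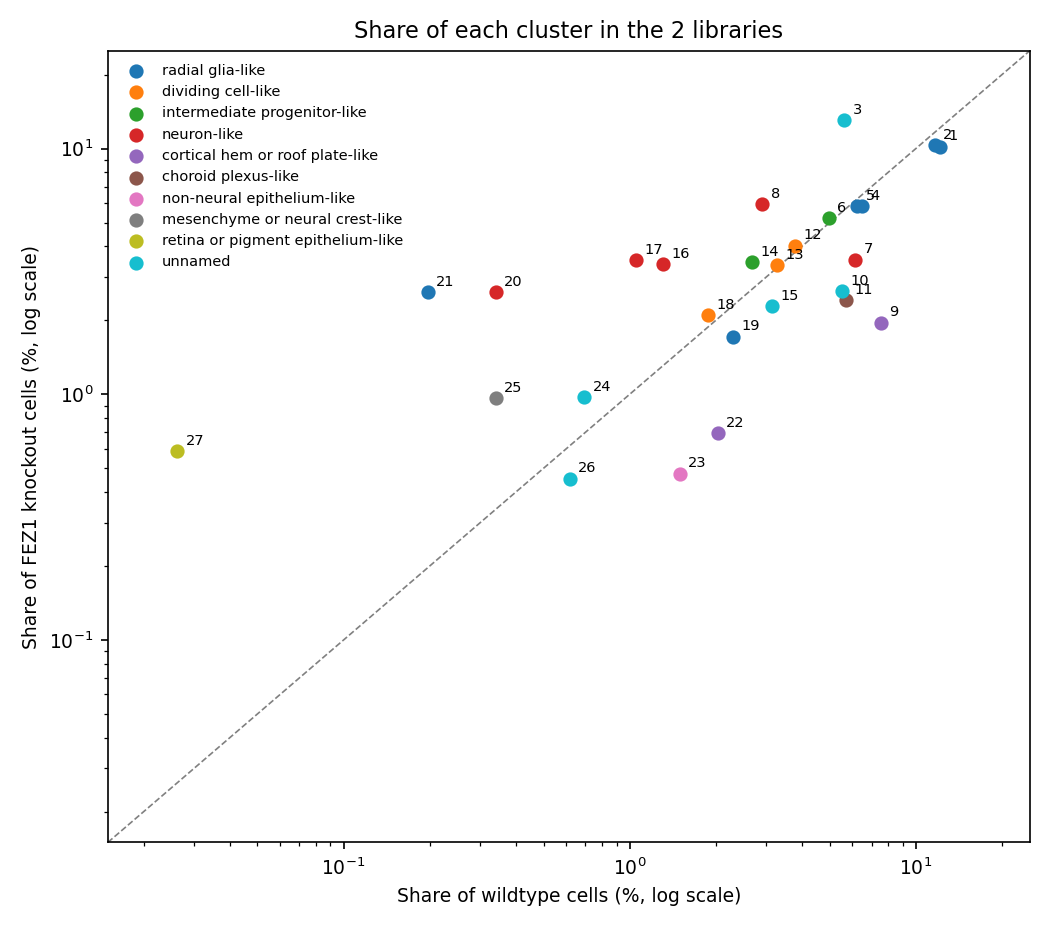
Share of kept cells (percent, log scale) of each of the 27 clusters in wildtype (horizontal axis) and FEZ1 knockout (vertical axis), 1 library each, coloured by class, with a dashed line of equal shares and no error bars. The cluster led by HOXB5 (number 20) held 0.341% of wildtype and 2.60% of knockout cells.

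Across the whole library, dorsal midline genes were lower in the knockout, and the intermediate progenitor, pan-neuronal and migration lists were higher. Of 13 measured members of the cortical hem and roof plate list, 9 were at least 1.5-fold lower and 0 higher (median log2 ratio -0.78, below all 10000 random lists). They included the Wnt co-activators RSPO1 (-1.54), RSPO2 (-1.42) and RSPO3 (-1.15) and WLS (-1.05), which carries Wnt proteins to the cell surface. Of 12 members of the BMP and TGF-beta list, 6 were lower, among them the BMP target genes ID1 (-0.81) and ID2 (132 and 65.8 CPM), and 1 was higher (median -0.38). In the choroid plexus list TTR stood at 4942 CPM in wildtype and 1402 CPM in the knockout (-1.82), and HTR2C, a serotonin receptor, at -1.71. IGFBP7 of the same list stood at 1.67, and the list's median was -0.58.

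Higher in the knockout library were CRYGD, a crystallin (45.8 and 116 CPM, log2 ratio 1.34, 1.29 to 1.40), NR2F2, a nuclear receptor of caudal and ventral forebrain (64.5 and 137 CPM, 1.08, 1.04 to 1.13), the TALE homeobox genes PBX3 (1.06) and MEIS2 (0.88), and the POU factor POU3F3 (0.79). LIMCH1 (0.93), C1orf21 (0.78), the fatty acid binding protein FABP5 (0.73), the long non-coding RNA MIAT (0.72) and IGDCC3 (0.71) completed the 10 largest. The lower end also held FAM89A (139 and 38.1 CPM, -1.87, -1.93 to -1.81), TPBG (-1.32), the calcium-binding protein S100A6 (-1.12) and ID3 (-0.79). Of 18 measured intermediate progenitor genes 6 were higher and 0 lower (median 0.36, above all random lists), led by the proneural factors NEUROD1 (1.14) and NEUROG1 (0.95) and by INSM1 (0.93). Of 28 pan-neuronal genes 5 were higher and 0 lower (median 0.43), among them the neurofilaments NEFL (0.76) and NEFM (0.68). The migration and axon guidance list had 8 higher and 2 lower of 30 (median 0.38), with the ephrin receptor EPHA3 at 1.23, the repellent SEMA3A at 1.19 and its co-receptor PLXNA2 at 0.98.

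Several other lists were close to equal. S phase (median -0.01, 28 members) and mitosis (0.03, 30 members) had 0 genes past 1.5-fold, as had cholesterol synthesis (0.03, 22 members), nuclear-encoded oxidative phosphorylation (-0.06, 34 members), the ventricular radial glia list (0.06, 27 members) and the stress response list (-0.03, 27 members). Not all were: the list of other glia, vessel, blood and muscle had 2 of 4 lower and 0 higher (median -0.71, but 0.00449 with no minimum level), CLDN5 at -1.18 and AIF1 at -1.02, and the GABAergic list had 2 of 5 higher and 1 lower (median 0.43). No cluster was named as immune or endothelial. AIF1 led an unnamed cluster (422 wildtype, 238 knockout cells), and CLDN5 was among the top 10 genes of the choroid plexus-like cluster (435 and 218). The mesenchyme list had 3 of 8 higher and 0 lower (median 0.51), with the matrix genes DCN at 2.57 and COL3A1 at 1.23, and the retina and pigment epithelium list had 2 of 9 higher, DCT (3.15) and PMEL (2.36), and 2 lower, TTR and OTX2 (-0.98), with a median of -0.06. The outer radial glia list had a median of 0.07, with SLC1A3, a glutamate transporter, at 1.53 and PALMD, among the top 10 genes of a hem-like cluster, at -1.56.

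In total 135 of 8758 genes were at least 1.5-fold higher and 95 at least 1.5-fold lower in the knockout library. Several of the lower genes, such as the RSPO genes, mark the hem-like and choroid plexus-like cells that were fewer in the knockout. When the class levels of both libraries were weighted by the wildtype class shares, RSPO2 moved to -0.16, RSPO3 to -0.04, TPBG to -0.17, ID1 to -0.21, ID2 to -0.50, ID3 to -0.32 and WLS to 0.0592, while TTR stood at -0.77, FAM89A at -1.15, S100A6 at -1.004, NR2F2 at 1.10 and CRYGD at 1.39. The hem list then had a median of -0.15 with 0 of 13 lower, still at percentile 0.01 of the random lists. The BMP list had a median of 0.04 and the choroid plexus list of 0.06. The pan-neuronal list had a median of 0.15 with 0 of 28 higher, the intermediate progenitor list of 0.23 with 4 of 18 higher, the migration list of 0.18 with 5 of 30 higher and the mesenchyme list of 0.15 with 1 of 6 higher. Class-naming markers are members of the hem, choroid plexus, pan-neuronal, intermediate progenitor and mesenchyme lists, so these moves toward equal were in part built in. Other lists moved away from equal. The GABAergic median went from 0.43 to 0.80 (3 of 5 higher) and the non-neural epithelium median from -0.03 to 0.45 (4 of 8 higher). The Cajal-Retzius median went from -0.06 to -0.34 and the retina and pigment epithelium median from -0.06 to -0.35. That weighting left 94 genes higher, 80 of them among the 135, and 42 lower, 33 of them among the 95.

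Within radial glia-like cells, NR2F2 stood at 22.6 CPM in wildtype and 91.8 CPM in the knockout (log2 ratio 2.03, 1.91 to 2.14). CRYGD (1.28, 1.21 to 1.36), the muscle-type LIM protein PDLIM3 (1.03), BNIP3, a mitophagy gene induced by low oxygen (1.03), and LIMCH1 (0.86) followed. Lower were S100A6 (-0.99, -1.09 to -0.90), ID2 (-0.77), EMX1, a homeobox gene of the dorsal cortex (139 and 82.6 CPM, -0.75, -0.82 to -0.68), the Notch effector HEY1 (-0.73) and MAGEA4 (-0.65). At 3000 UMIs per cell NR2F2 was found in 6.08% of wildtype and 19.97% of knockout radial glia-like cells, at median depths of 10828 and 8246 UMIs. Unthinned, the shares were 19.5% and 40.9%, and no compared class lacked the gene. EMX1 was found in 33.0% of wildtype and 20.3% of knockout radial glia-like cells at 3000 UMIs, and in 3.02% and 0.498% of choroid plexus-like cells (median depths 13339 and 9517.5 UMIs), which should lack it. Unthinned, EMX1 was found in 75.1% and 42.4% of radial glia-like cells. EMX1 was the 1 lower gene of 16 in the dorsal telencephalon list there, with 0 higher and a median of 0.07. That list includes markers that named the class.

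Genes of hypoxia and glycolysis were higher in knockout radial glia-like cells, 4 of 22 by at least 1.5-fold and 0 lower (median 0.32, above all random lists). These were BNIP3, the lactate dehydrogenase LDHA (0.78), the glucose transporter SLC2A1 (0.70) and the collagen hydroxylase P4HA1 (0.70). The Wnt list had 3 of 19 higher and 0 lower (median 0.23), namely the ligand WNT7A (1.05), the receptor FZD8 (0.99) and DKK3 (0.74). Of 11 genes in the list of outer radial glia, basal progenitors of the cortex, SLC1A3 (1.55) and TKTL1 (0.72) were higher and BMP7 (-1.02) was lower (median 0.28), with PTPRZ1 at 0.55. SLC1A3 and PTPRZ1 were also among the markers that named radial glia-like cells, and BMP7 among those for hem-like cells. These values therefore do not show a change in outer radial glia. The ventricular radial glia list, which includes markers that named the class, had a median of 0.14, with 1 of 27 higher. Migration and guidance genes had 5 of 22 higher and 2 lower (median 0.23), with EPHA3 at 1.06, EPHA7 at 0.91 and EFNA5 at -0.82. HEY2 (-1.09) and HEY1 were lower in the Notch list, whose median was -0.02, and in the non-neural epithelium list KRT8 (-1.23) and KRT18 (-0.99) were among the 3 lower of 4. That list was not low in radial glia-like cells alone. Its median was -0.99 there, -0.96 in dividing, -1.09 in intermediate progenitor-like, -0.66 in neuron-like and -0.44 in hem-like cells, but 0.44 in choroid plexus-like cells. Free RNA in the droplets, measured above with TTR, was not separated from these values. The p53 list had 2 of 17 lower, PHLDA3 (-0.92) and ZMAT3 (-0.60).

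By size 102 of 8505 genes were higher and 56 lower in knockout radial glia-like cells. Without the cluster of 15 wildtype and 236 knockout cells, 89 were higher, 88 of them the same genes, and 56 lower, 53 the same. BNIP3 then stood at 0.73, and the hypoxia and glycolysis list had a median of 0.21 with 2 of 22 higher. This took out only part of the cells that were mostly knockout. At resolution 2.0 the radial glia-like cells that were kept included parts led by LIMCH1 and PMP2 (20 wildtype, 246 knockout cells) and by SLC1A3, PMP2 and BNIP3 (34 and 226), so the differences within radial glia-like cells were not separated from that mix.

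Neuron-like cells of the knockout library carried more transcripts of ventral and posterior neurons and fewer of most measured Cajal-Retzius and dorsal telencephalon genes. The clusters that the naming rule took as Cajal-Retzius neurons went both ways, but the name was less sure for 1 of them. That led by NEUROD6 and RELN held 468 wildtype and 319 knockout cells, and that led by BARHL2 and LHX9 held 80 and 318. The latter had 7 of 10 Cajal-Retzius markers raised but only 1, BARHL2, among its top 10 genes. BARHL2 and LHX9 are also in the diencephalon, midbrain and hindbrain list, so its larger knockout count is not by itself a gain of Cajal-Retzius neurons. Of 10 measured GABAergic and ventral telencephalon genes 9 were higher and 0 lower (median 3.12, above all random lists), including the homeobox gene DLX5 (4.89), the neuropeptide SST (7.98 and 146 CPM, 4.19, 3.84 to 4.57), DLX6-AS1 (3.69) and SIX3 (3.40). All markers that named the GABAergic cluster are members of this list, so its median in part restates the larger knockout count of that cluster. The SST value rested on 41 of 1713 knockout and 5 of 896 wildtype cells, with 1322 of 1393 knockout UMIs in 34 cells of the GABAergic cluster, and was 1.16 with doublets kept. Of 6 diencephalon, midbrain and hindbrain genes 4 were higher and 1 lower (median 1.10), with HOXB2 at 3.84, IRX2 at 2.13 and FOXP2 at -1.03. That median was 0.14 with no minimum CPM. Cajal-Retzius genes were lower in 8 of 14 and higher in 2 (median -0.67), with RELN, the secreted protein that guides cortical layering, at 84.9 and 29.2 CPM (-1.54, -1.75 to -1.34), CALB2 at -1.41 and EBF2 at -1.21. Dorsal telencephalon genes were lower in 9 of 17 and higher in 2 (median -0.61), among them EMX1 (-0.79), DMRTA2 (-0.77) and EMX2 (-0.76). Deep-layer and upper-layer cortical neuron genes were higher in 6 of 19 and lower in 2 (median 0.11).

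By the rule for single genes, the neuropeptide NTS (-1.78), RSPO3 (-1.68) and ZIC2 (75.6 and 31.8 CPM) were also lower, and ZFHX3 (1.53) and PBX3 (1.47) higher. HOXB5 stood at 0 and 118 CPM. The cortical hem and roof plate list, which holds RSPO3 and ZIC2, had a median of -0.88 with 4 of 6 lower and 0 higher. Free RNA from hem-like cells was not separated from these values. In the migration and guidance list 6 of 38 were higher and 1 lower (median 0.24), with the commissural axon receptor ROBO3 at 3.02. The pan-neuronal list, which includes markers that named the class, had a median of 0.07 with 0 of 28 higher and 1 lower, and the synapse list a median of 0.10. Oxidative phosphorylation genes had a median of -0.26 with 0 of 34 past 1.5-fold. Mitosis genes were lower in 4 of 6 (median -1.17), with TOP2A at -1.79, a median that was 0.00751 when each cell had equal weight.

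In size terms 219 of 8642 genes were higher and 208 lower in knockout neuron-like cells. Within the NEUROD6 and RELN cluster alone, 321 were higher, 67 of them among the 219, and 374 lower, 117 of them among the 208. There 1 GABAergic gene was measured, at -1.24, ZFHX3 stood at -0.0193 and PBX3 at 0.43, short of 1.5-fold. Dorsal telencephalon genes were lower in 8 of 17 and higher in 1 (median -0.19). Cajal-Retzius genes were lower in 7 of 14 and higher in 1 (median -0.61). RELN (-0.84), CALB2 (-1.19), NTS (-0.73) and RSPO3 (-0.67) were lower. This cluster was itself a mix that differed between the libraries. At resolution 2.0 its cells fell into clusters led by NEUROD6 and NEUROD2 (138 wildtype, 140 knockout cells), by NTS and FOXP2 (135 and 44), by LHX1, LHX5 and RELN (104 and 23) and by TAC3 (86 and 104).

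**Figure D4:**
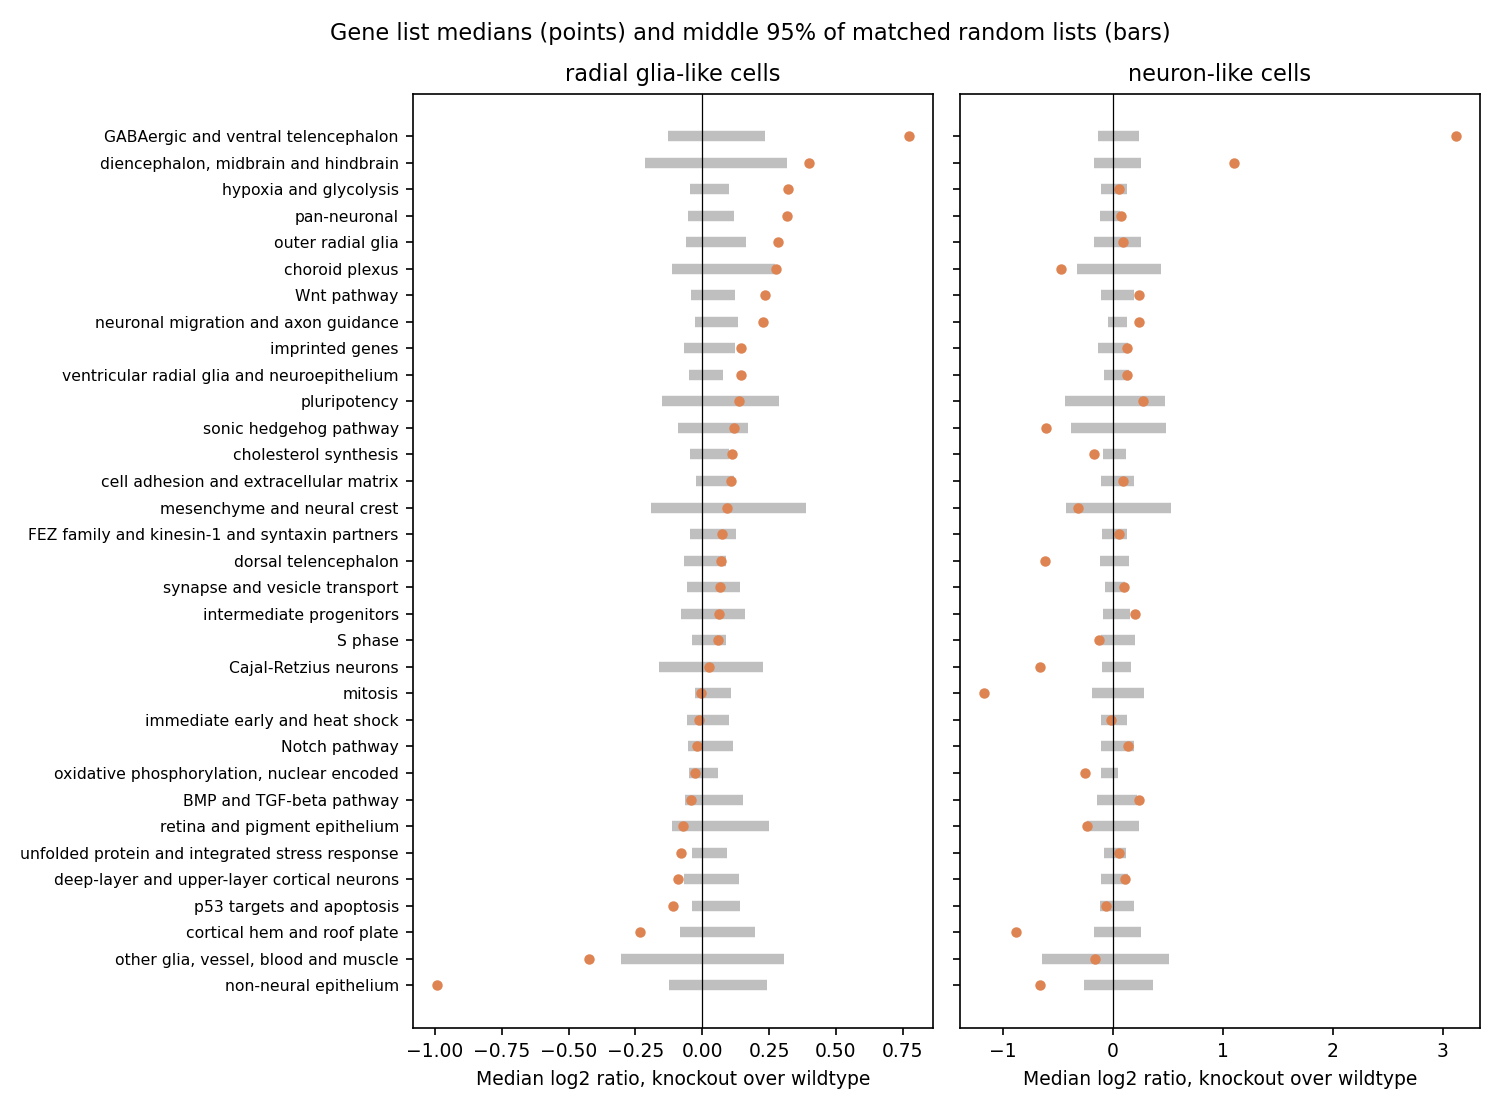
Median log2 ratio of CPM, FEZ1 knockout over wildtype, of each gene list (points) in radial glia-like (left) and neuron-like cells (right), from 1 library per group; grey bars are the middle 95% of matched random lists and not an interval over replicates. The GABAergic list stood at 3.12 in neuron-like cells and the hypoxia and glycolysis list at 0.32 in radial glia-like cells.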

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

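Both tests of free FEZ1 RNA and those of doublets and of lysed cells were chosen only after the results they bear on were seen.

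For 3 gene lists the medians were at least 1.5-fold from equal in opposite directions in different classes, in each case a difference that was not tested. Only lists with at least 3 measured members in a class were taken. Other lists had opposite medians that did not both pass 1.5-fold. Mitosis genes had a median log2 ratio of 1.12 over 13 members in choroid plexus-like cells and -1.17 over 6 members in neuron-like cells. The median in neuron-like cells was 0.00751 when each cell had equal weight, so that opposition depended on the weighting. The choroid plexus-like median was not separated from a mix seen at resolution 2.0. Its parts were led by TTR (332 wildtype, 138 knockout cells) and by CCNO (97 and 79). GABAergic genes had a median of 3.12 over 10 members in neuron-like cells and -0.82 over 3 members in intermediate progenitor-like cells. Cajal-Retzius genes had a median of 0.69 over 4 members in choroid plexus-like cells and -0.67 over 14 members in neuron-like cells.

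The knockout library kept FEZ1 transcripts at 23.6% of the wildtype level, and unedited cells mixed in would have left some knockout neuron-like cells at the full wildtype level, but 0.0790% (0.0020 to 0.439) had 3 or more FEZ1 UMIs at 3000 UMIs per cell, against 1.35% for a mixture (wildtype 8.06%). Free RNA as the only source would have given each cell a like number of FEZ1 UMIs, but knockout neuron-like cells held 1.51 times as many per cell as radial glia-like cells (1.35 to 1.69), and 2.49 times the CPM (2.23 to 2.79) where like numbers would give 1.65. Free RNA as a part of it stays open, since the knockout-to-wildtype ratio in choroid plexus-like cells, low in FEZ1, was 2.10 times that in neuron-like cells (1.49 to 2.97). Nonsense-mediated decay of an edited transcript stays open too: in the cluster led by SNHG12 and other hosts of small nucleolar RNAs, known decay targets, the ratio was 2.18 times that in radial glia-like cells (1.81 to 2.63), above 99.9% of 7295 genes, which free RNA could also give. Against a link to those genes, choroid plexus-like cells, which they do not lead, gave 1.97 times, and SNHG12 itself stood at 207 CPM in knockout and 384 CPM in wildtype cells of the cluster.

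HOXB5 and HOXB6 UMIs were found only in the knockout library, while HOXB2 had 80 in wildtype and 538 in the knockout. Wildtype or other unedited cells carried into it would hold wildtype FEZ1 levels, but FEZ1 in the knockout cells of the HOXB neuron cluster was 19.7% (16.0 to 24.1) of that in wildtype neuron-like cells. Doublets would hold more RNA, but the median UMI count was 1.09 times that of other knockout neuron-like cells. Organoids of the same genotype may differ as much in regional identity, and with 1 library per group this cannot be told apart from an effect of the genotype, which also stays untested.

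The cluster led by SNHG12, with few mitochondrial UMIs and high stress genes such as DDIT3, held 5.61% of wildtype and 13.0% of knockout cells. The difference remained within a range of UMI counts: among cells of 5000 to 10000 UMIs the cluster's share was 16.5% (15.4 to 17.7) in the knockout and 8.88% (7.86 to 9.98) in wildtype, a ratio of 1.86. That range lay below the wildtype median of 10120 UMIs and around the knockout median of 7092. Cells were not clustered again at a fixed depth, so a part played by lower depth was not excluded. Lysed cells or bare nuclei would be rich in the nuclear RNA MALAT1, which stood at 1.48 times the radial glia-like level in the knockout and 1.56 in wildtype, on either side of the 1.5 times set as the bound, so that bound decided nothing. A criterion on ribosomal protein UMIs was added once these values and the medians were known: the cluster's lower quartile (25.2% knockout, 26.9% wildtype, under medians of 31.2% and 32.6%) lay above the radial glia-like median (24.6% and 26.2%) by a small margin. As the medians were known when this criterion was set, it was no test of lysis, which stays open. A difference in stress during culture or dissociation and an effect of the genotype both stay open, and no test of either was made. Other clusters with stress genes went both ways. The unnamed cluster led by AIF1, with GDF15 and DDIT3 among its top 10 genes, held 5.53% of wildtype and 2.63% of knockout cells. The radial glia-like cluster led by CHAC1 held 12.1% and 10.2%, and the neuron-like cluster led by ATF5 and DDIT3 held 2.91% and 5.93%.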

How the results depend on the processing

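Leaving out clusters, the denominator of named cells, the NEUROD6 and RELN cluster alone and the per-cell mean for gene lists were chosen after seeing the data. No paired analysis was possible because each group had replicate 1 only. In all 9 alternatives for class shares, neuron-like, intermediate progenitor-like, mesenchyme-like and pigment epithelium-like cells held a larger share in the knockout, and hem-like and choroid plexus-like cells a smaller one. For the values below the cause was not tested unless stated. FEZ1 was -1.96 with the mean of per-cell CPM and -2.16 with 1 class mix. Differences in share are in percentage points. With no cell filter they were -0.831 for dividing, 0.146 for intermediate progenitor-like, -8.84 for hem-like and -1.99 for choroid plexus-like cells. With at least 1000 genes and at most 10% mitochondrial UMIs they were 0.0837 for radial glia-like cells, reversed, -2.34 for dividing and -5.41 for hem-like cells. With doublets kept, hem-like cells stood at -8.95 and epithelium-like cells reversed to 0.173. At Leiden resolution 0.5, hem-like cells stood at -8.09, choroid plexus-like cells at -6.02 and epithelium-like cells at 0.188, reversed. At resolution 2.0, neuron-like cells stood at 3.14, hem-like cells again at -8.09 and epithelium-like cells at 0.188, where 1093 of 1102 hem-like cells and all 17 epithelium-like cells were the same as at 0.5. Centring each library gave 2.94 for intermediate progenitor-like, 4.85 for neuron-like, -5.31 for hem-like and -4.08 for choroid plexus-like cells. Leaving 4285 genes 2-fold apart out of the variable genes, 1604 of which were left, gave -2.33 for choroid plexus-like cells. The marker score gave 2.37 for radial glia-like cells, reversed, -2.11 for dividing, 1.87 for intermediate progenitor-like, -7.93 for hem-like and -2.54 for choroid plexus-like cells, with 2988 of 16666 cells within 0.1 of the next class. Over named cells only, by construction a smaller denominator, the values were -0.939 for radial glia-like, 9.59 for neuron-like and -8.06 for hem-like cells. Of whole-library genes, 207 were higher with the mean of per-cell CPM, 4412 higher and 3185 lower with no minimum, 16 and 25 at 50 CPM or more, where fewer genes could pass, and 42 lower with 1 class mix, where WLS reversed to 0.0592. Intermediate progenitor-like cells had 118 genes higher with doublets kept, against 252 as reported, with 80 in both. Neuron-like cells had 363 higher with the per-cell mean and, in the NEUROD6 and RELN cluster alone, 374 lower, with ZFHX3 reversed to -0.0193 and the GABAergic list, of 1 gene there, and the diencephalic list, of 4, reversed to -1.24 and -0.11. Lists with a median at least 1.5-fold from equal numbered 1 in the whole library with 1 class mix, 0 in radial glia-like cells and 3 in neuron-like cells with no minimum, and 3 in neuron-like cells with the per-cell mean, against 2, 2 and 8 as reported. With the per-cell mean the epithelium and mitosis lists in neuron-like cells reversed to 0.0936 and 0.00751. With no minimum the sonic hedgehog list there reversed to 0.23 and the list of other glia, vessel, blood and muscle in the whole library to 0.00449. Cells with a FEZ1 UMI were 15.7% in wildtype and 4.42% in the knockout at 1500 UMIs, and 60.7% and 18.7% without thinning, as depth sets such shares.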

Other observations

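Values in classes other than radial glia-like and neuron-like cells, and those inside single clusters, were chosen only after they were seen.

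In intermediate progenitor-like cells 252 genes were higher and 143 lower in the knockout. With doublets kept, which changed the clusters, 118 were higher, 80 of them among the 252, and 115 lower, 55 of them among the 143. Of 27 pan-neuronal genes 10 were higher and 0 lower (median log2 ratio 0.35), among them NEFM (1.60), the microtubule regulator STMN2 (0.73) and MAP2 (0.65). Of 31 migration and guidance genes 11 were higher and 1 lower (median 0.43), with EPHA3 at 1.82 and ROBO3 at 1.68, and EFNA5 at -1.28. EOMES, the defining factor of cortical intermediate progenitors, stood at 0.99. The Notch list had 3 of 17 lower and 0 higher (median -0.19), namely HEY2 (-1.80), HEY1 (-1.38) and HES1 (-0.85). The BMP and TGF-beta list had 3 of 8 lower and 0 higher (median -0.17), namely ID3 (-1.77), ID1 (-1.49) and ID2 (-0.64), and S phase genes had a median of -0.23 with 3 of 22 lower. A cluster led by CNTN2 and NHLH1, genes of later stages, held 204 of 582 wildtype and 311 of 781 knockout cells of the class, and these differences were not separated from that mix. In dividing cells the mitosis list, which includes all markers that named that class, was at 0.00. There 5 of 14 intermediate progenitor genes were higher, with INSM1 at 1.79, NEUROG1 at 1.57 and EOMES at 1.51.

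Hem-like and choroid plexus-like cells, fewer in the knockout, were also compared in content. Of the hypoxia and glycolysis genes, 5 of 21 were higher and 0 lower in hem-like cells, and 11 of 27 higher and 1 lower in choroid plexus-like cells, with SLC2A1 at 1.58 and 2.16 and LDHA at 1.39 and 1.57. Choroid plexus-like cells were themselves a mix. At resolution 2.0 they held parts led by TTR (332 wildtype, 138 knockout cells) and by CCNO (97 and 79), and differences within them were not separated from it. Mitosis genes were higher in 8 of 30 in hem-like cells (median 0.43), among them MKI67 at 0.89 and CENPF at 0.82, but this was not separated from the mix of clusters, as a dividing cluster held 155 of 731 wildtype and 63 of 240 knockout hem-like cells. HOPX, a marker of outer radial glia, stood at 1.79 in hem-like cells. The hem list itself was close to equal there (median 0.18, 1 of 19 higher and 0 lower), with GDF7, a BMP ligand, at 0.87. All markers that named hem-like cells are members of that list, so near-equality there was in part built in. These classes held 240 and 218 knockout cells, and in total 360 genes were higher and 157 lower in hem-like cells (255 and 218 with median-of-ratios scaling), and 667 and 161 in choroid plexus-like cells (487 and 238).

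Inside the NEUROD6 and RELN cluster, 11 of 18 deep-layer and upper-layer genes were higher in the knockout (median 0.74), including SOX5 (1.30), NEUROD2 (1.22) and BCL11B (0.81), with NEUROD1 at 1.36. RGS16 (-2.01), DACH1 (-1.87), FOXP2 (-1.79), FABP7 (-1.50) and LHX5, a Cajal-Retzius factor (-1.34), were lower. At resolution 2.0 the cluster split into parts led by LHX1, LHX5 and RELN (104 wildtype, 23 knockout cells), by NTS and FOXP2 (135 and 44) and by NEUROD6 and NEUROD2 (138 and 140), so these differences were not separated from that mix. Cells with under 2% mitochondrial UMIs were 12.7% of wildtype and 27.3% of knockout cells.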
